A study of Mus musculus with 48 samples.

How the data were processed

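Messenger RNA of the tibialis anterior muscle was sequenced from both legs of male C57BL/6 mice. Per the labels, polyadenylated RNA was made into directional paired-end libraries and sequenced on an Illumina NovaSeq instrument. The 48 libraries fall into 8 groups of 6, given by age, injection and leg. Groups and mouse numbers were taken from the sample labels. The series design text names 4 aged vehicle mice, whereas the labels and the deposited tables hold 6, and all 6 were used here.

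The authors deposited 6 tables, each with 57010 genes by Ensembl identifier and the libraries of 2 groups. The deposited values are log2 values, named by the authors as regularized logarithms (rlog); this transformation scales libraries for their size and shrinks values toward the gene's mean where counts are low. The submitters' processing notes name STAR 2.7.10a, DESeq2 1.30.1 and the genome build GRCm39, with no role stated for each. The counter and the gene annotation are not given in the sources used here. Raw counts were not used here, so the depth of each library is unknown and no counting interval can be given; precision is described by the spread between mice. Because of the shrinkage, log2 changes are on the rlog scale and understate the change of genes with low counts.

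Each table was transformed separately by the authors. Where the same library stands in 2 tables, the SD over genes of the difference between its values was 0.102 to 0.164, and the median difference -0.075 to 0.086. All tests were therefore made within a table, and differences in effect between ages or between treatments were not tested. Gene symbols were taken from GENCODE mouse release M21, matched on the Ensembl identifier without its version; that annotation is of an earlier build, so no coordinates are given. Of the genes tested, 218 to 238 per table had no symbol. Reads of near-identical copies (Hspa1a and Hspa1b, Orm1 and Orm3, the globin genes) can be divided between the copies by the counting, so their separate values are uncertain.

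The comparisons were 6. Dexamethasone was compared with vehicle in the non-stimulated legs of young and of aged mice, between different mice. The stimulated leg was compared with the non-stimulated leg in each of the 4 treatment and age groups, with the mouse as a block, since both legs of a mouse share its number. The correlation between the deviations of the 2 legs of a mouse from their group means had a median of 0.43 in young vehicle, 0.40 in young dexamethasone, 0.28 in aged vehicle and 0.36 in aged dexamethasone mice, against -0.04, -0.16, -0.08 and -0.05 between legs of different mice. Genes with a mean value of at least 3 over the table (about 8 reads) were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 changes are the standard errors of that fit; group values are means with the SD over 6 libraries.

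A total of 32 gene lists of pathways and cell type markers, with 387 genes, were fixed, and 3 of their symbols (Bmal1, Atp5f1a, Atp5f1b) matched no gene; Arntl, the other name of Bmal1, did. For each list the members called over all genes tested and those adjusted over the list alone were counted. Lists were also tested with camera of limma at a preset correlation between genes of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a table. Gene sets raised or lowered by dexamethasone were tested with camera in the contraction tables, as 16 tests adjusted together. Overlaps of called genes were tested with Fisher's exact test, two-sided. Where a set and a contraction table share non-stimulated libraries, chance was simulated with 100 draws of unchanged groups and the test was repeated with the sets taken from mice 1 to 3 and the contraction change from mice 4 to 6, and the reverse.

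Genes were named by a rule: in each comparison the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, or whose 6 mice all moved the same way in paired tables; up to 4 members with the smallest p of each list described; and always Nr3c1, Fkbp5, Tsc22d3, Klf15, Ddit4, Fbxo32, Trim63, Fos, Egr1, Atf3, Ankrd1 and Ppargc1a. Predicted genes, pseudogenes and genes without a symbol were left out of the first part. Not every gene that the rule names is described in the text. The groups, comparisons and their tests, camera with both correlations, lists, naming rule and the first set of alternatives were chosen before the data were examined; tests of single patterns were chosen later.

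The alternatives were no filter on low values, a minimum mean of 6, centring of libraries on their medians, quantile normalization, no intensity trend, array weights, a minimum absolute log2 change of 0.5, an adjusted p under 0.01 for the dexamethasone sets and overlap, the fit with the replicate number as a block or without it, and leaving out each mouse in turn. The alternatives for gene lists were added later. The fit was tested on simulated data with 200 changed genes per table: of 100 genes changed by a log2 value of 0.5, 80% and 82% were called in the young and aged dexamethasone tables, 91% and 96% in the young vehicle and young dexamethasone contraction tables, and 97% and 90% in the aged vehicle and aged dexamethasone contraction tables. With a log2 change of 1, 96% to 100% were called, and 3.2% to 6.7% of calls were false. The changed genes were drawn at random and the noise was independent between genes, so these shares do not hold for genes that vary much between mice. Csrp3, higher by 1.3 with contraction in 6 of 6 young vehicle mice, was not called (limma adjusted p 0.47). A count of 0 calls is therefore no sign that no gene changed by 0.5. Figures were drawn in Python 3.11.15.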

Results

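Messenger RNA was measured in the tibialis anterior, a muscle of the lower leg, of young (4 months) and aged (24 to 25 months) male mice. Each mouse received saline vehicle or 2 mg/kg of dexamethasone, a synthetic glucocorticoid, and 2 h later the muscles of 1 leg were made to contract while being lengthened, by 10 sets of 6 stimulations of the sciatic nerve at 100 Hz. Both muscles were taken 4 h after the contractions, which was 6.5 h after the injection. Age, injection and leg gave 8 groups of 6 libraries, 48 in all. Values are rlog values on the log2 scale, and the depth of the libraries is unknown. The p-values of limma measure the spread between mice, and with contraction that of the difference between legs. Those of Fisher's exact test and of camera at the preset correlation take genes as independent or nearly so, which they are not.

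The 12 libraries of the young dexamethasone comparison were placed by their mean over 517 genes that dexamethasone raised in the aged mice, with the mean of the vehicle libraries at 0% and that of the other 5 dexamethasone libraries at 100%. Vehicle libraries lay between -12.6% and 24.8%, and dexamethasone libraries 1, 2, 4, 5 and 6 between 94% and 103.5%. The library of young dexamethasone mouse 3 lay at -4.4%. It was kept in every comparison.

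The first comparison asked which genes dexamethasone changed in the resting muscle of young mice. Pnmt (ENSMUSG00000038216.8), which encodes the enzyme that makes adrenaline, rose from 7.17 ± 0.52 to 9.57 ± 0.35 (mean ± SD of 6 mice each), a change of 2.39 ± 0.22 (SE; limma adjusted p 0.00014). Gnmt (ENSMUSG00000002769.10), a glycine methyltransferase that uses S-adenosylmethionine, rose by 1.79 ± 0.10 (adjusted p 1.06e-06). Orm1 and Orm3, which encode acute-phase plasma proteins, rose by 1.46 ± 0.10 and 1.22 ± 0.20 (adjusted p 7.21e-06 and 0.012); as near-identical copies their separate values are uncertain. Among named genes whose groups did not overlap, the largest fall was that of Cldn5 (ENSMUSG00000041378.3), a tight-junction protein of endothelial cells, from 8.78 ± 0.42 to 7.71 ± 0.27, a change of -1.07 ± 0.18 (adjusted p 0.0124). Timp4, a metalloproteinase inhibitor, changed by -0.91 ± 0.14, Nrarp, a gene regulated by Notch, by -0.86 ± 0.13 and Cpeb1, a regulator of polyadenylation, by -0.78 ± 0.08 (adjusted p 0.0116, 0.00934 and 0.000214). Ptprf, a receptor phosphatase, and Cdkal1, a transfer RNA modifying enzyme, rose by 1.34 ± 0.20 and 1.31 ± 0.17 (adjusted p 0.00802 and 0.00254). Egfl7, secreted by endothelial cells, fell by 0.70 ± 0.12 (adjusted p 0.017), and Arntl, the clock factor BMAL1, fell by 0.93 ± 0.21 (adjusted p 0.0439).

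In young mice 131 genes rose and 60 fell of 14049 tested, 191 in all, 18 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2109 genes, against 702 by chance. The groups did not overlap for 225 genes (1.6%, against 0.22% by chance). The count was 674 without dexamethasone mouse 3, with all 191 among them, and 108, 79 and 104 without vehicle mice 1, 2 and 4. It was 92, 105, 84, 71 and 66 without dexamethasone mice 1, 2, 4, 5 and 6. Several glucocorticoid-induced genes did not pass: Ddit4, an inhibitor of mTORC1 signalling, was higher by 1.78 ± 0.56 (adjusted p 0.149), Fkbp5, a chaperone of the receptor, by 0.78 ± 0.29 (0.217) and Klf15 by 0.60 ± 0.25 (0.275). Without dexamethasone mouse 3 their changes were 2.35, 1.06 and 0.85 (adjusted p 0.000463, 0.00306 and 0.00286), the lowest over the alternatives, which reached 0.3, 0.41 and 0.504. Nfkbia (1.01, adjusted p 0.00105, up to 0.165 over the alternatives), Hspb8 (-1.05, 0.0489, up to 0.423) and Cd163 (0.43, 0.0216, up to 0.54) also passed without that mouse. The named genes called with it, except Timp4, Il1r2 and Cd14, moved further without it, among them Pnmt (2.51), Ptprf (1.51), Cdkal1 (1.46), Orm3 (1.40) and Cldn5 (-1.18). Tsc22d3 (0.18), Trim63 (0.12), Fbxo32 (-0.08), Nr3c1 (0.03), Ppargc1a (-0.15), Ankrd1 (-0.66), Atf3 (-0.77), Fos (-0.12) and Egr1 (0.13) did not pass (adjusted p 0.348 to 0.956).

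Of the 32 gene lists, 27 had no called member in young mice; 5 passed camera at the preset correlation and none at the estimated one. Of 21 glucocorticoid targets none was called over all genes and 3 rose adjusted over the list alone; their median change was 0.41 (camera adjusted p 4.02e-05 at the preset correlation and p 0.96 at the estimated one). Of 10 endothelial markers 2 fell, Cldn5 and Egfl7, and 4 fell adjusted over the list alone, with a median of -0.22 (p 0.00869 and, estimated, p 0.994). Of 15 clock genes Per2 rose (0.44 ± 0.09, adjusted p 0.0375) and Arntl and Nr1d1 (-0.98 ± 0.22, adjusted p 0.0457) fell, with 3 higher and 4 lower adjusted over the list alone; their median was 0.12 and their mean -0.01, and camera pointed upward (adjusted p 0.353). Of 11 macrophage markers Cd14 rose (0.42 ± 0.08, adjusted p 0.0202), with a median of 0.27 (p 0.00628 and, estimated, p 0.96). Of 13 heat shock genes none was called, with a median of -0.38 (p 0.00645 and, estimated, p 0.994), and of 10 slow fibre genes none, with a median of 0.43 (p 0.00214 and, estimated, p 0.96). Herpud1 of the unfolded protein response (0.37 ± 0.08, adjusted p 0.04) and Il1r2 of the neutrophil markers (0.38 ± 0.08, adjusted p 0.0359) also rose.

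Those clock, immune and unfolded protein calls depended on the libraries used. Without dexamethasone mouse 3 all were kept (adjusted p 0.0148 for Arntl, 0.0194 for Per2, 0.00495 for Nr1d1, 0.00655 for Herpud1, 0.0233 for Il1r2 and 0.0139 for Cd14). In the runs that ended them the changes stayed at -0.98 to -0.86 for Arntl, 0.42 to 0.47 for Per2, -1.02 to -0.80 for Nr1d1, 0.32 to 0.38 for Herpud1, 0.33 to 0.39 for Il1r2 and 0.38 to 0.40 for Cd14. The call of Arntl ended without vehicle mice 2, 3, 4 and 5 (adjusted p 0.0727, 0.0541, 0.0676 and 0.08) or dexamethasone mice 1, 2, 4, 5 and 6 (0.0952, 0.0796, 0.0845, 0.111 and 0.108), over a range of 0.0109 to 0.111. That of Per2 ended without vehicle mice 2, 4 and 5 (0.0897, 0.0703 and 0.0665) or dexamethasone mice 1, 2, 4, 5 and 6 (0.0522, 0.067, 0.0919, 0.0992 and 0.0997), over 0.00638 to 0.0997. That of Nr1d1 ended without vehicle mice 1, 2, 4 and 5 (0.0551, 0.102, 0.0746 and 0.0803) or dexamethasone mice 1, 2, 4, 5 and 6 (0.0936, 0.0899, 0.102, 0.114 and 0.112), over 0.00457 to 0.114. Herpud1 lost its call without vehicle mice 1, 2 and 5 (0.0603, 0.0943 and 0.0719) or dexamethasone mice 1, 2, 4, 5 and 6 (0.0853, 0.084, 0.0845, 0.0983 and 0.104; range 0.00655 to 0.104), and Il1r2 without vehicle mice 1 to 5 (0.0688, 0.0717, 0.0584, 0.0571 and 0.0598) or dexamethasone mice 1, 4 and 6 (0.067, 0.0845 and 0.0805; range 0.0233 to 0.0845). Cd14 lost it without vehicle mouse 2 (0.0595) or dexamethasone mouse 6 (0.0559), over 0.011 to 0.0595. Pnmt, Gnmt, Orm1, Orm3, Ptprf, Cdkal1, Cldn5, Timp4, Nrarp and Cpeb1 kept theirs in every alternative that tested them (Orm1 and Orm3 lay under the minimum mean of 6), Orm3 up to an adjusted p of 0.0347 and Cldn5 up to 0.0403; Egfl7 lost its call only with the replicate number as a block (0.0511; range 0.00115 to 0.0511).

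**Figure D1:**
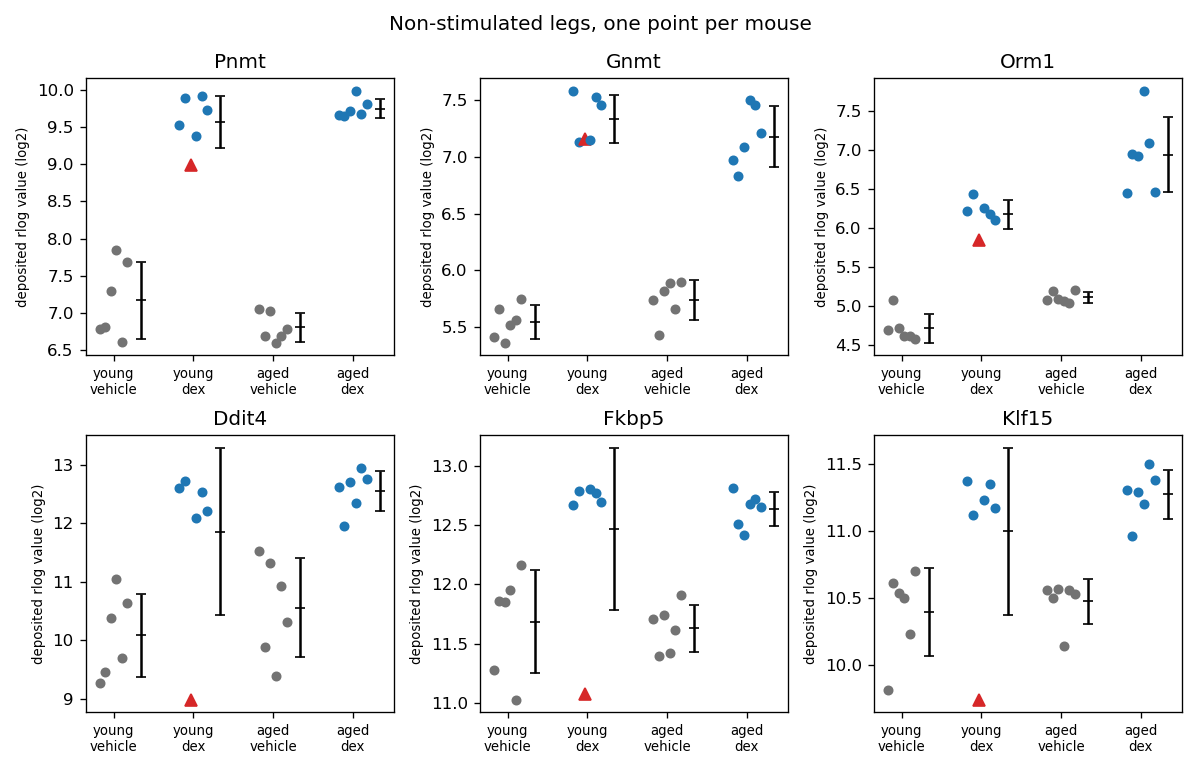
Values (log2, rlog) of Pnmt, Gnmt, Orm1, Ddit4, Fkbp5 and Klf15 in the non-stimulated leg of each mouse of the 4 groups, with mean and SD. The triangle is young dexamethasone mouse 3, at 8.98 for Pnmt, 8.98 for Ddit4 and 11.08 for Fkbp5; ages were transformed separately.

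The second comparison asked the same in aged mice. Lcn2 (ENSMUSG00000026822.15), a lipocalin that binds bacterial siderophores, rose from 7.53 ± 0.66 to 10.74 ± 0.46 (mean ± SD of 6 mice each), a change of 3.21 ± 0.28 (SE; limma adjusted p 8.75e-06). Pnmt rose from 6.81 ± 0.19 to 9.75 ± 0.13, a change of 2.94 ± 0.09 (adjusted p 7.06e-11). Greb1, Odf3l2 and Orm1 rose by 2.19 ± 0.13, 2.18 ± 0.20 and 1.83 ± 0.17 (adjusted p 1.87e-07, 1.38e-05 and 1.55e-05), and Ddit4 by 2.00 ± 0.31 (0.00127). Among called genes whose groups did not overlap, the largest fall was that of Ppp1r27 (ENSMUSG00000025129.3), from 10.28 ± 0.19 to 8.69 ± 0.39, a change of -1.59 ± 0.15 (adjusted p 2.4e-05). Nmrk2, a nicotinamide riboside kinase, changed by -1.24 ± 0.17, Bcl6b by -1.07 ± 0.09, Pcdh12, a protocadherin of vessels, by -0.84 ± 0.06 and Igfbp5, which binds insulin-like growth factors, by -0.80 ± 0.12 (adjusted p 0.000393, 1.1e-05, 1.74e-06 and 0.00108). Fam110b fell by 0.93 ± 0.14 (adjusted p 0.000835).

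In aged mice 529 genes rose and 298 fell of 14029 tested, 827 in all, 46 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2640 genes, against 701 by chance. The groups did not overlap for 510 genes (3.64%, against 0.22% by chance). The count fell to 541 without dexamethasone mouse 5. Fkbp5 rose by 1.00 ± 0.09, Klf15 by 0.80 ± 0.09 and Trim63, a ubiquitin ligase of atrophy, by 0.50 ± 0.10 (adjusted p 1.24e-05, 0.000107 and 0.00963). Tsc22d3 (0.20, adjusted p 0.159), Ppargc1a (-0.21), Nr3c1 (-0.04), Fbxo32 (-0.03), Ankrd1 (-0.77), Atf3 (-0.84), Fos (-0.30) and Egr1 (-0.48) did not pass.

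Of 21 glucocorticoid targets 12 rose in aged mice, among them Sesn1 (0.96 ± 0.08, adjusted p 8.3e-06), Fkbp5, Klf15 and Nfkbia (1.04 ± 0.12, 0.000127); 16 rose adjusted over the list alone, with a median of 0.58. This list alone passed camera with an estimated correlation (adjusted p 0.0151; preset 9.94e-16). Of 18 atrophy and autophagy genes 5 rose, Foxo1 (0.69 ± 0.09, 0.000399), Depp1 (1.03 ± 0.20, 0.00747), Bnip3 (0.36 ± 0.07), Foxo3 (0.36 ± 0.07) and Trim63, and 6 adjusted over the list alone (camera preset p 0.0249, estimated p 0.576). Of 13 genes that restrain mTORC1, Sesn1, Klf15 and Ddit4 rose, with 4 higher and 1 lower adjusted over the list alone (p 0.0257, estimated p 0.576). Sesn1, Klf15 and Ddit4 are also members of the glucocorticoid target list, so their rise is not a separate result. Of 10 endothelial markers 5 fell, Egfl7 (-0.56 ± 0.09, adjusted p 0.00124), Cldn5 (-0.61 ± 0.12, 0.0094), Pecam1 (-0.32), Tie1 (-0.29) and Tek (-0.37), and 6 adjusted over the list alone, with a median of -0.31 (p 0.0071, estimated p 0.576). Of 15 clock genes Per2 (0.68 ± 0.09, adjusted p 0.000448), Ciart (0.58) and Per3 (0.48) rose and Bhlhe41 (-0.77 ± 0.10, 0.000384) and Nr1d1 (-0.62) fell; 8 rose and 4 fell adjusted over the list alone (p 0.135). Of 22 immediate early genes Nr4a1 (0.61 ± 0.08, 0.000366), Maff (0.82) and Zfp36 (0.73) rose and 1 fell, with 3 higher and 1 lower adjusted over the list alone; the median was -0.04, the mean -0.02 and the camera test upward (p 0.731). Of 8 Nrf2 targets Gsr fell (-0.25), and 2 adjusted over the list alone (p 0.0249, estimated p 0.867). In all, 7 lists passed camera at the preset correlation. Lists without a called member numbered 16, with medians of -0.66 to 0.63. Of all 32 lists, 19 had a member that passed adjusted over the list alone. Among those without a called member, polyamine metabolism had 3 lower adjusted over the list alone (camera p 0.0257, estimated p 0.742). Nr1d1 lost its call without vehicle mouse 5 (adjusted p 0.0506) or dexamethasone mice 1 and 6 (0.0533 and 0.0514).

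The third comparison asked whether the same genes were called at both ages, among 13786 genes tested in both. Of 126 genes raised in young and 517 in aged mice 89 were shared, against 4.7 for independent lists (Fisher's exact test, two-sided, odds ratio 74.1, p 1.71e-99). Of 60 and 294 lowered genes 34 were shared, against 1.3 (odds ratio 67.7, p 9.41e-42). None was called in opposite directions by limma. All 126 young calls that were higher and 58 of 60 that were lower had the same sign in aged mice. Across genes, which are not independent replicates, Spearman's rho was 0.56. The total of 123 shared genes was 409 without young dexamethasone mouse 3 and 61, 49, 66 and 67 without young vehicle mice 1, 2, 4 and 5. It was 51, 65, 50, 42 and 42 without young dexamethasone mice 1, 2, 4, 5 and 6; it was not run without an aged mouse. A difference in response between ages was not tested, since the tables were transformed separately.

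**Figure D2:**
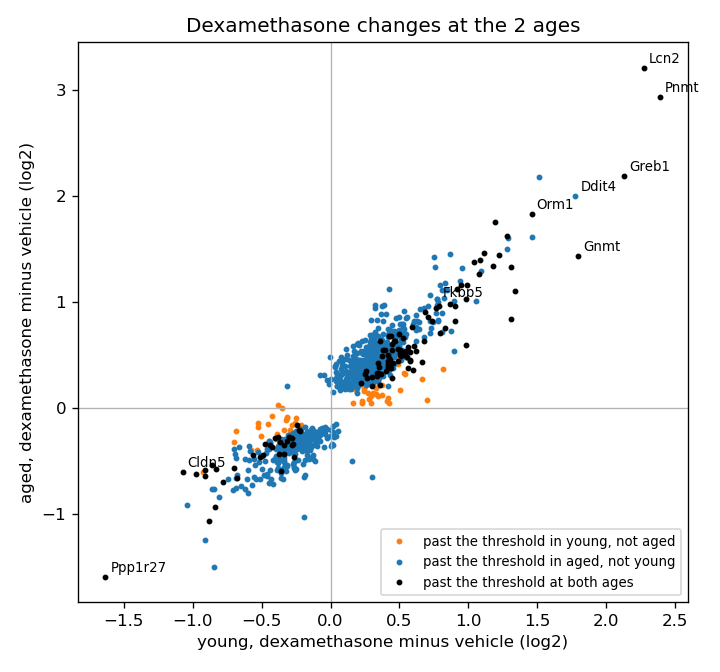
Change with dexamethasone (log2) in young (horizontal) and aged (vertical) non-stimulated muscle, one point per called gene. The 89 genes raised and 34 lowered at both ages lie along the diagonal.

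Contraction was compared between the legs of the same mouse, first in aged vehicle mice. Csrp3 (ENSMUSG00000030470.16), a LIM protein of the Z-disc, rose by 2.41 ± 0.39 (SE; limma adjusted p 0.0267) in 6 of 6 mice, by 0.75 to 4.31. Enah, a regulator of actin, rose by 2.20 ± 0.30, Otud1, a deubiquitinase, by 2.06 ± 0.28, Ccn1, a secreted matricellular protein, by 1.79 ± 0.27, Ankrd1 by 1.45 ± 0.24 and Atf3 by 1.29 ± 0.19 (adjusted p 0.0217, 0.0217, 0.0235, 0.0267 and 0.0235), each in 6 of 6 mice. Hspa1a and Hspa1b, near-identical genes of inducible HSP70 whose separate values are uncertain, rose by 1.96 ± 0.37 and 2.12 ± 0.39 (adjusted p 0.0372 and 0.0364). Among genes that fell, Agt, the angiotensin precursor, changed by -0.39 ± 0.08, Mn1 by -0.39 ± 0.05, Klf15 by -0.37 ± 0.07, Pdxk, a vitamin B6 kinase, by -0.37 ± 0.07 and Snai3 by -0.36 ± 0.06 (adjusted p 0.0468, 0.0217, 0.0362, 0.0347 and 0.0343). Every call named here ended without mouse 2, 3, 5 or 6; that of Agt also ended without mouse 1 (0.0714) or 4 (0.0713), and that of Snai3 without mouse 1 (0.0579).

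In aged vehicle mice 250 genes rose and 23 fell of 14224 tested, 273 in all, 31 by at least 2-fold; 2813 had an unadjusted p under 0.05, against 711 by chance. All 6 mice moved the same way for 1911 genes (13.44%, against 3.12% by chance). No gene was called by limma without mouse 2, 3, 5 or 6 (smallest adjusted p 0.0714, 0.0598, 0.0521 and 0.0939), nor with no filter on low values (0.057). Fos (1.43 ± 0.45, adjusted p 0.14), Egr1 (0.73), Fkbp5 (-0.20, 0.0777), Fbxo32 (-0.43), Ddit4 (-0.18), Tsc22d3 (-0.15), Trim63 (-0.03), Nr3c1 (0.03) and Ppargc1a (-0.12) did not pass.

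Of 15 mechanical stress and sarcomere genes 9 rose in aged vehicle mice, among them Flnc (0.99 ± 0.15), Xirp1 (1.42 ± 0.22) and Hspb7 (0.61 ± 0.10; adjusted p 0.0235, 0.0239 and 0.0262), and 12 adjusted over the list alone; the median was 0.85 (camera preset adjusted p 4.2e-12, estimated p 0.497). Of 13 heat shock genes 5 rose, including Hspb8 (0.72 ± 0.08, adjusted p 0.018) and Hspb1 (1.16 ± 0.19, 0.0267), and 11 adjusted over the list alone, with a median of 0.89 (p 1.17e-10, estimated p 0.497). Of 22 immediate early genes Atf3 and Fosl1 (0.93 ± 0.19) rose, with 9 higher and 1 lower adjusted over the list alone (p 0.00124, estimated p 0.511). Of 21 glucocorticoid targets Per1 (0.42 ± 0.07), Cdkn1a (0.40 ± 0.07) and Sesn1 (0.40 ± 0.08) rose and Klf15 fell, and 6 rose and 3 fell adjusted over the list alone; their median was -0.05, their mean 0.03 and the camera test upward (p 0.947). Musk, a kinase of the neuromuscular junction (0.47 ± 0.06, adjusted p 0.018), Cxcl10 (1.42 ± 0.23, 0.0267), Cd68 (0.71 ± 0.12, 0.0326), Gabarapl1 (0.55 ± 0.07, 0.0196) and Nr1d1 (0.68 ± 0.11, 0.0267) also rose. As above, every call ended without mouse 2, 3, 5 or 6, and without mouse 1 those of Per1 (adjusted p 0.0529), Cdkn1a (0.0546) and Sesn1 (0.0535) also ended, as did that of Cdkn1a without mouse 4 (0.0506). In all, 15 lists passed camera at the preset correlation, 11 upward and 4 downward, and none at the estimated one. Lists without a called member numbered 17, and 21 of all 32 lists had a member that passed adjusted over the list alone. Among those without a called member, 12 extracellular matrix genes had a median of 0.40 and 2 higher adjusted over the list alone (camera p 0.00124, estimated p 0.497).

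The same comparison in young vehicle mice gave no call by limma, with 927 of 14084 genes at an unadjusted p under 0.05 (704 by chance) and a smallest adjusted p of 0.452; without mouse 1 there were 14 calls, and under the other alternatives none. Csrp3 was higher in 6 of 6 mice, from 10.66 ± 0.51 to 11.96 ± 0.81 (mean ± SD; limma adjusted p 0.47), Dcn, a matrix proteoglycan, in 6 of 6 by 0.38 ± 0.08 (SE; 0.47), Fn1 in 5 of 6 by 0.44 ± 0.09 (0.467), Atf3 in 4 of 6 by 0.75 ± 0.24 (0.712) and Ankrd1 in 4 of 6 by 0.70 ± 0.38 (0.799). Klf15 (-0.12), Fkbp5 (-0.09), Fbxo32 (-0.28) and Fos (0.36) did not pass. All 6 mice moved the same way for 472 genes (3.35%, against 3.12% by chance). Of 15 mechanical stress genes 10 were higher adjusted over the list alone, with a median of 0.53 (p 1.3e-10, estimated p 0.449), as were 6 of 7 fibroadipogenic markers (median 0.22; p 1.29e-07, estimated p 0.322), 6 of 12 matrix genes (0.30; p 1.29e-07, estimated p 0.449) and 3 of 8 tendon markers (0.35; p 8.02e-06, estimated p 0.453). The 10 interferon genes were all lower on average, with a median of -0.14 (p 1.72e-05, estimated p 0.454). Of the 4 with the smallest p, Ifit1 (-0.84 to 0.04) and Gbp2 (-1.36 to 0.12) were lower in 3 of 6 mice. Ifi44 and Usp18 were lower in 4 of 6.

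In young dexamethasone mice no gene was called by limma either, with 1357 of 13990 at an unadjusted p under 0.05 (700 by chance) and a smallest adjusted p of 0.0855. There were 91 calls without mouse 3, 1 without mouse 5, 1 without mouse 6, 3 after quantile normalization and 4 with array weights. Fmod and Thbs4, tendon matrix genes, were higher in 6 of 6 mice by 0.93 ± 0.14 and 0.57 ± 0.10 (limma adjusted p 0.18 each), Col1a1 in 6 of 6 by 0.42 ± 0.08 (0.191), Hspb7 in 5 of 6 by 0.47 ± 0.09 (0.242), Csrp3 in 5 of 6 by 0.84 ± 0.23 (0.279), Atf3 in 5 of 6 by 0.92 ± 0.21 (0.275) and Ankrd1 in 5 of 6 by 0.82 ± 0.31 (0.424). Klf15 (-0.01), Fkbp5 (-0.06) and Fos (-0.27) did not pass. All 6 mice moved the same way for 756 genes (5.4%, against 3.12% by chance). Of 15 mechanical stress genes 10 were higher adjusted over the list alone, with a median of 0.36 (p 7.95e-09, estimated p 0.52), as were 7 of 8 tendon markers (0.34; p 3.29e-08, estimated p 0.288) and 3 of 15 clock genes (0.04; p 0.00116, estimated p 0.288). Of 10 interferon genes 3 were lower adjusted over the list alone (median -0.14; p 3.31e-06, estimated p 0.564), and of 9 inflammatory mediators 3 (-0.20; p 0.000541, estimated p 0.564).

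In aged dexamethasone mice no gene was called by limma, with 1129 of 14052 at an unadjusted p under 0.05 (703 by chance) and a smallest adjusted p of 0.0695. There were 132 calls without mouse 2, 1 with array weights and 1 without the mouse as a block. Csrp3 was higher in 6 of 6 mice by 1.86 ± 0.28 (limma adjusted p 0.217), Atf3 in 6 of 6 by 1.59 ± 0.32 (0.247), Lmcd1, a LIM domain protein, in 6 of 6 by 0.68 ± 0.14 (0.247), Xirp1 in 5 of 6 by 1.44 ± 0.33 (0.263) and Ankrd1 in 5 of 6 by 1.35 ± 0.38 (0.316). Fbxo32, a ubiquitin ligase of atrophy, was lower in 6 of 6 by -0.38 ± 0.09 (0.263), and Klf15 in 5 of 6 by -0.23 ± 0.09 (0.515). All 6 mice moved the same way for 618 genes (4.4%, against 3.12% by chance). Camera at the preset correlation passed 10 lists, 8 upward and 2 downward, and at the estimated one 0. Of 15 mechanical stress genes 9 were higher adjusted over the list alone, with a median of 0.47 (p 7.09e-13, estimated p 0.676), as were 3 of 13 heat shock genes (0.61; p 2.58e-08, estimated p 0.7), 3 of 11 macrophage markers (0.23; p 1.33e-07, estimated p 0.7) and 3 of 7 fibroadipogenic markers (0.13; p 8.15e-05, estimated p 0.7).

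**Figure D3:**
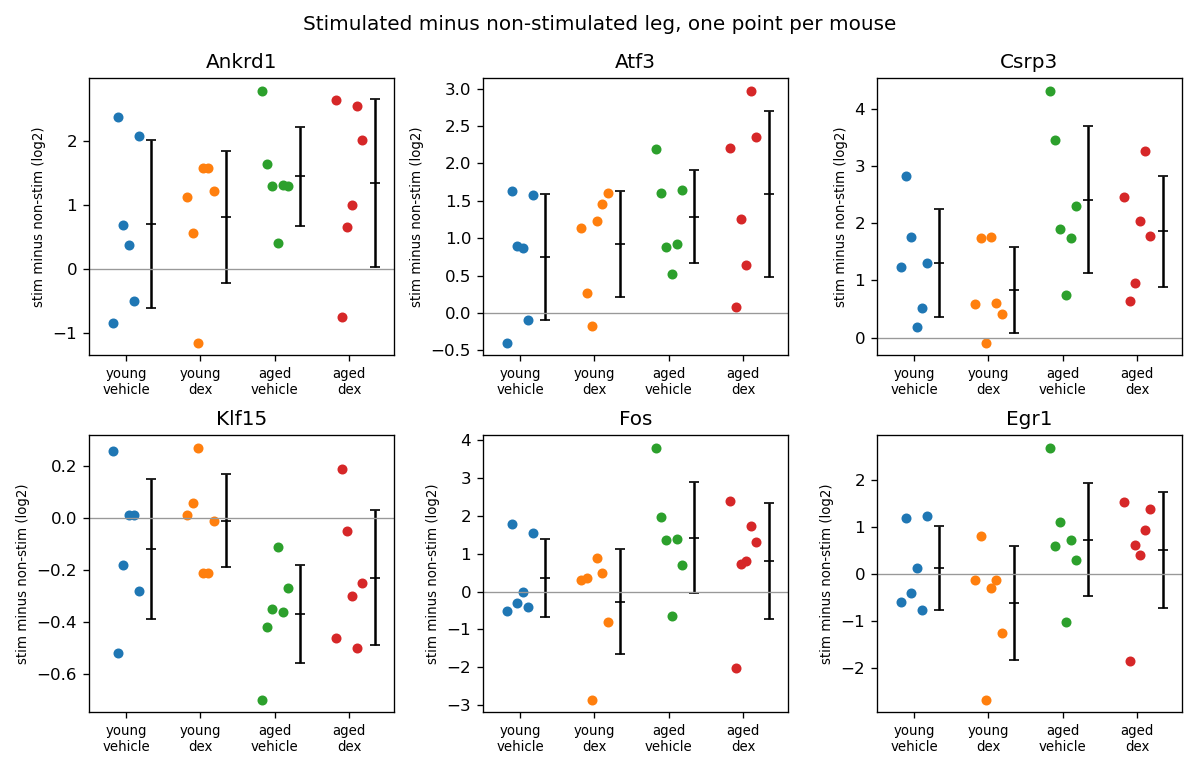
Stimulated minus non-stimulated leg (log2) of Ankrd1, Atf3, Csrp3, Klf15, Fos and Egr1, one point per mouse, with mean and SD, in the 4 groups. Csrp3 was higher in 6 of 6 mice in young vehicle, aged vehicle and aged dexamethasone mice and in 5 of 6 young dexamethasone mice.

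No gene was called by limma in more than 1 contraction comparison, since 3 of the 4 had none, so the overlaps of calls could not be tested; without the mouse as a block, 1 gene was called in aged vehicle and aged dexamethasone mice. The counts at an unadjusted p under 0.05 were 927, 1357, 2813 and 1129 in young vehicle, young dexamethasone, aged vehicle and aged dexamethasone mice. Across genes, which are not independent replicates, Spearman's rho of the changes was 0.61 between young and aged vehicle mice, 0.37 between young and aged dexamethasone mice, 0.43 between treatments in young and 0.50 in aged mice. Whether contraction acted differently by age or treatment was not tested, since the tables were transformed separately.

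The last comparison asked how contraction moved the genes sensitive to dexamethasone, such as Klf15. Of 500 tested genes raised by dexamethasone in aged mice 14 rose and 6 fell with contraction in aged vehicle mice, and of 298 lowered genes 16 rose and 3 fell. Over all 14224 genes tested 250 rose and 23 fell. These calls ended without mouse 2, 3, 5 or 6 (0 calls each). Of the 500 raised genes 300 were higher in the stimulated leg (median 0.022, camera p 0.0154, estimated p 0.324). Both comparisons hold the same non-stimulated vehicle libraries, which alone can tilt raised genes upward. The other 3 contraction comparisons had 0 calls by limma. Of 16 camera tests 6 passed at the preset correlation, with median changes of -0.011 to 0.044, and none with an estimated one (adjusted p 0.195 to 0.324 for these 6). In young dexamethasone mice 46 of 60 genes lowered by dexamethasone at that age were higher in the stimulated leg (median 0.044, p 1.91e-05, estimated p 0.195) and 82 of 131 raised genes were lower (-0.011, p 0.0309, estimated p 0.324). With the sets taken at an adjusted p under 0.01, which hold fewer genes, the first turned (median -0.02) and the second (-0.027) no longer passed. These share the non-stimulated libraries. With the sets taken from mice 4 to 6 and contraction from mice 1 to 3, 51% of 239 raised genes were lower, against 51.3% of all genes, and 39.4% of 66 lowered genes were lower; the reverse left 8 and 2 genes. In aged dexamethasone mice 187 of 290 genes lowered at that age were higher (median 0.021, p 0.00064, estimated p 0.324). With separate mice 42.5% of 40 and 45.4% of 227 lowered genes were lower, against 52.7% and 49.3% of all genes, and 40.4% of 178 and 41.6% of 433 raised genes. The Pearson correlation across genes of the dexamethasone and contraction changes was -0.22 in young dexamethasone mice, against -0.35 simulated with no effect, and -0.22 and -0.01 with separate mice. In aged dexamethasone mice it was -0.08 against -0.42, and 0.06 and 0.08. In young and aged vehicle mice it was 0.03 against 0.42 and 0.03 against 0.39, and with separate mice -0.19 and -0.18, and 0.06 and -0.21. The simulated groups held no dexamethasone effect, whereas the real ones did, so the sizes of these correlations are not comparable. The covariance was -0.00328, -0.00162, 0.000413 and 0.000899 in young dexamethasone, aged dexamethasone, young vehicle and aged vehicle mice. Simulated means were -0.00175, -0.00271, 0.00255 and 0.00226. The covariance differed from the simulated one by -0.00152, 0.00109, -0.00214 and -0.00136 in these 4 groups. With no shared library, 320 of 505 genes raised in aged mice were higher with contraction in young vehicle mice (median 0.024, p 0.000645, estimated p 0.324), and 168 of 291 lowered genes in young dexamethasone mice (0.013, p 0.0154, estimated p 0.324).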

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

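The 3 tests of young dexamethasone mouse 3 in this part were chosen only after the result was seen. Of 472 groups of 6 libraries or mice checked, 40 had 1 value far from the other 5; chance gives about 1 in 20, which is 24. Of the 40, 13 came from young dexamethasone mouse 3. The values of that library in the dexamethasone comparison, with the range of the other 5 mice of its group, were Ddit4 8.98 (12.09 to 12.72), Fkbp5 11.08 (12.67 to 12.8), Klf15 9.74 (11.12 to 11.37), Nfkbia 9.93 (10.97 to 11.29), Trim63 14.15 (14.85 to 15.21) and Fbxo32 13.06 (13.42 to 13.59), all lower. Cldn5 8.21 (7.49 to 7.76), Ankrd1 14.19 (11.65 to 12.54), Hspb8 15.01 (13.52 to 13.97), Dnaja1 10.81 (9.9 to 10.16) and Nr1d1 11.97 (10.95 to 11.2) were higher. With contraction the same mouse differed in Ankrd1 (-1.15; others 0.57 to 1.58) and Col1a2 (1.03; others 0.23 to 0.41).

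The non-stimulated library of young dexamethasone mouse 3 lay with the vehicle libraries over 517 genes raised by dexamethasone in aged mice, at -0.14 against the highest vehicle library. A wrong label or a fault of that library alone was excluded, since the stimulated leg of mouse 3 also lay below the lowest of the other 5 stimulated legs (-0.36, with a range of 0.05 among these), and so was a swap with a young vehicle mouse, since no vehicle library was out of place: the lowest of the other dexamethasone libraries lay 0.333 above the highest vehicle library. What stays open therefore concerns the mouse, for example that it was a vehicle mouse, or that its dose was missed or not absorbed. Both predict vehicle values over the 517 genes and were not tested apart. Other explanations that concern the mouse were not tested. Pnmt (8.98), Gnmt (7.16) and Orm1 (5.85), looked at after their values were seen, lay above all 6 vehicle libraries (highest 7.84, 5.75 and 5.08). They were named among genes whose groups did not overlap, which requires that place, so it decides nothing. The rule did not set how far above they lay. Gnmt lay within the other 5 dexamethasone libraries (7.13 to 7.58), and Pnmt and Orm1 below these. Of 41 genes raised at least 2-fold in aged mice, 8 lay above all vehicle libraries in mouse 3. The count was up to 12 for a vehicle library over the other 5 and at least 36 for the other dexamethasone libraries. These values leave the question open. No biological explanation was tested, since the labels give none.

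The other values far from their group are given here with the range of the other 5. In the young dexamethasone comparison they were Orm1 in vehicle mouse 2 (5.08; 4.58 to 4.72), Orm3 in vehicle mouse 4 (4.01; 3.88 to 3.92) and Bag3 in vehicle mouse 1 (14; 12.78 to 13.11). In the aged dexamethasone comparison vehicle mouse 4 was apart in Ankrd1 (13.84; 12.36 to 12.88), Klf15 (10.14; 10.5 to 10.57), Nr4a2 (5.56; 5.01 to 5.21) and Azin1 (10.96; 10.02 to 10.37), dexamethasone mouse 2 in Fos (10.59; 7.48 to 8.59) and Sms (11.64; 11.3 to 11.41), and dexamethasone mouse 4 in Sesn1 (10.88; 10.51 to 10.57).

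With contraction, the difference between legs was far from the other mice in young vehicle mouse 1 for Fn1 (-0.08; 0.42 to 0.65), Col6a1 (-0.28; 0.38 to 0.68) and Mmp2 (-0.32; 0.32 to 0.52), and in mouse 3 for Cspg4 (0.77; 0.06 to 0.29). In young dexamethasone mouse 4 it was so for Ppargc1a (-0.33; 0.01 to 0.18). In aged vehicle mice it was so in mouse 1 for Ucp3 (-1.12; -0.38 to -0.26), Slc2a4 (-0.36; -0.18 to -0.09) and Pdgfra (0.54; 0.18 to 0.31), in mouse 4 for Cd79a (-0.46; -0.06 to 0.03), and in mouse 5 for Mmp2 (0.92; 0.11 to 0.39), Col6a1 (1.31; 0.1 to 0.3) and Col3a1 (2.6; 0.21 to 0.59). In aged dexamethasone mouse 2 it was so for Egr1 (-1.85; 0.41 to 1.54), Irs2 (-0.52; 0.19 to 0.57), Usp18 (-0.31; -0.1 to 0.01), Gbp2 (-1.92; -0.19 to 0.08) and Isg15 (-0.91; -0.15 to 0.16).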

How the results depend on the processing

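The alternatives for gene lists and the runs of the overlap without 1 mouse were chosen only after the data had been seen; the estimated correlation was fixed earlier as a second value and was only then added to the alternatives. Depth is unknown, since the deposited values hold no counts, so its limits could not be measured; rlog values shrink weakly expressed genes. Of the values of named genes, 2519 kept direction and side of the threshold with 1 mouse left out and 2721 with another setting, whereas 233 and 114 lost their call, 48 and 21 gained one and 32 and 5 reversed. Of gene list tests 378 and 267 were the same, 52 and 30 lost their call and 2 reversed. No scaling moved the median of all genes by over 0.1. For gene sets a reversal is one of the direction of camera; the medians lay near 0 and their signs are given where they did not turn. For the changes below the cause was not tested, unless the alternative itself tests fewer genes or mice.

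With no filter on low values, more genes were tested and the calls were 83 in young and 509 in aged dexamethasone comparisons and 0 with contraction in aged vehicle mice. With a mean of at least 6, fewer genes were tested: dexamethasone called 102 genes in young mice, the overlap was 66, 6 gene lists passed with contraction in aged dexamethasone mice, the set raised by dexamethasone in young mice had a median of -0.009 in young dexamethasone mice and no longer passed, and camera turned for the set lowered in aged mice in aged vehicle mice, passing in neither run, while the median stayed negative (-0.001). With a change of at least 0.5 required, the calls were 80 and 296 for dexamethasone in young and aged mice and 108 for contraction in aged vehicle mice.

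With array weights, dexamethasone called 697 genes and 8 gene lists in young mice, and contraction called 4 genes in young dexamethasone, 475 in aged vehicle and 1 in aged dexamethasone mice; Fos reversed in young dexamethasone mice (0.023) and Trim63 in aged vehicle mice (0.027). With quantile normalization, 3 genes were called in young dexamethasone mice, and Trim63 reversed in young vehicle (-0.035) and young dexamethasone mice (-0.02). With libraries centred on their medians, Ddit4 reversed in young dexamethasone mice (0.008). The set lowered in aged mice (0.025) no longer passed there, and in aged vehicle mice camera turned for the sets lowered in young (-0.019) and aged mice (-0.011), passing in neither run, while both medians stayed negative.

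With the replicate block, dexamethasone called 110 genes in young mice, and no other count moved by over 1.5 times. Arntl, Egfl7, Herpud1, Per2, Nr1d1, Il1r2 and Cd14 lost their calls in young mice. So did Igf1r, Nr4a2, Cox6a2, Cd14 and Mkx in aged mice, where Amd1 and Azin1 gained one. That block pairs different mice by number alone. Deviations of same-numbered libraries had a median correlation of -0.02 in young and 0.1 in aged mice. With no replicate block, contraction called 1 gene in aged dexamethasone mice, 1 gene was shared with aged vehicle mice, and 9 gene lists passed in aged vehicle mice. The sets raised in young mice (-0.011) and lowered in aged mice (0.013) in young dexamethasone mice and the set raised in aged mice in aged vehicle mice (0.022) no longer passed, and camera turned there for the set lowered in aged mice, passing in neither run, with the same median (-0.005). The overlap of dexamethasone calls was taken from fits with no block, so that alternative changes nothing there, and it was not run with one.

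With calls at an adjusted p under 0.01, the overlap was 10 and the dexamethasone sets held fewer genes. In young vehicle mice the set raised in young mice (-0.005) reversed, camera turned for that lowered in young mice while its median stayed negative (-0.076), passing in neither run, and that raised in aged mice (0.018) no longer passed. In young dexamethasone mice the set raised in young mice (-0.027) no longer passed and that lowered in young mice (-0.02) reversed. In aged vehicle mice the sets raised in young (-0.004) and lowered in aged mice (0.016) reversed and that raised in aged mice (0.017) no longer passed, and in aged dexamethasone mice the set lowered in young mice (-0.031) reversed. With the estimated correlation 0 gene lists passed in every comparison but dexamethasone in aged mice, with 1, and the 6 sets with medians of 0.024, -0.011, 0.044, 0.013, 0.022 and 0.021 no longer passed.

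With each mouse left out in turn, the calls for dexamethasone ranged from 66 (without dexamethasone mouse 6) to 674 (mouse 3) in young mice and from 541 (dexamethasone mouse 5) to 963 in aged mice, with 4 (vehicle mouse 4) to 12 (dexamethasone mouse 2) gene lists in aged mice; the overlap ranged from 42 to 409 with each young mouse left out (dexamethasone mice 5 and 3) and was not run without an aged mouse. With contraction the calls were 0 to 14 (mouse 1) in young vehicle, 0 to 91 (mouse 3) in young dexamethasone, 0 (mice 2, 3, 5 and 6) to 360 in aged vehicle and 0 to 132 (mouse 2) in aged dexamethasone mice, with 6 (mouse 4) to 14 gene lists in the last. The immediate early list in young dexamethasone mice had an adjusted p of 0.00103 to 0.858 and reversed without mouse 3, and the interferon list in aged dexamethasone mice one of 0.00103 to 0.927 and reversed without mouse 2. Changes of genes near 0 spanned both signs. With dexamethasone these were Fos (-0.572 to 0.191), Nr3c1 (-0.007 to 0.063), Trim63 (-0.017 to 0.259) and Egr1 (-0.248 to 0.492) in young mice, and Fos (-0.717 to 0.099) and Fbxo32 (-0.116 to 0.09) in aged mice. With contraction they were Nr3c1 (-0.007 to 0.054), Trim63 (-0.102 to 0.067), Tsc22d3 (-0.112 to 0.005) and Egr1 (-0.087 to 0.312) in young vehicle mice, and Ddit4 (-0.064 to 0.091), Fos (-0.501 to 0.248) and Klf15 (-0.071 to 0.026) in young dexamethasone mice. In aged vehicle mice they were Trim63 (-0.091 to 0.058), and in aged dexamethasone mice Nr3c1 (0, just negative before rounding, to 0.094), Tsc22d3 (-0.023 to 0.082) and Isg15 (-0.209 to 0.005).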

Other observations

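The tests of endothelial markers, of the spread between mice and of the genes raised by contraction in aged vehicle mice were chosen only after the result was seen; the regroupings of libraries were planned. Genes with large changes in aged dexamethasone mice were also called in young mice, although their groups overlapped there. Lcn2 rose by 2.27 in young mice (limma adjusted p 0.0252), Greb1 by 2.13 (0.0116) and Ppp1r27 changed by -1.63 (0.0285). These were chosen after their values were seen, and no alternative was run for them in young mice. Klf15, which contraction lowered in aged vehicle mice (-0.37), rose with dexamethasone in aged mice (0.80). Its contraction call ended without mouse 2 (adjusted p 0.11), 3 (0.096), 5 (0.0868) or 6 (0.117), over a range of 0.0163 to 0.117.

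Of 249 tested genes that contraction raised in aged vehicle mice, 245 were higher with contraction in young vehicle mice (median 0.22, camera estimated p 0.143), 229 in young dexamethasone mice (0.13, estimated p 0.13) and 245 in aged dexamethasone mice (0.30, estimated p 0.0622). None of these genes was called there by limma, where 927, 1357 and 1129 genes had an unadjusted p under 0.05. The tables were transformed separately and the differences were not tested. With dexamethasone in young mice, which share no library with that comparison, 174 of 248 of these genes were lower, 2 rose and 3 fell (median -0.12, preset p 0.00029, estimated p 0.621). In aged mice, which share the non-stimulated vehicle libraries, 14 of 247 rose and 16 fell, with a median of -0.06 (preset p 0.0346, estimated p 0.661).

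Of 10 endothelial markers 2 fell with dexamethasone in young and 5 in aged mice, with medians of -0.22 and -0.31; as a list they did not pass camera with an estimated correlation (p 0.994 and 0.576). Fewer endothelial cells in the sample would lower all markers alike only if other cells and the rlog shrinkage affected each marker equally. The changes ranged from -1.07 to 0.14 in young and from -0.61 to 0.20 in aged mice. No other regrouping of the libraries reached this spread (exact permutation p 0.00216 at each age, the smallest possible). The markers thus did not fall alike, but fewer endothelial cells are not excluded, since an equal fall need not follow from them. Regulation of single genes such as Cldn5 remains a hypothesis that was not tested.

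Contraction gave 273 calls by limma in aged vehicle mice, which ended without mouse 2, 3, 5 or 6 (0 calls each), and none in young vehicle, young dexamethasone and aged dexamethasone mice, where 927, 1357 and 1129 genes had an unadjusted p under 0.05 and leaving out mouse 1, 3 and 2 gave 14, 91 and 132 calls. The median residual SD over all genes tested, with the mouse as a block, reflects how far the difference between legs varied between mice. In aged vehicle mice it lay 0.0111 above that of young dexamethasone mice, also with any mouse left out. Over all genes the spread was thus not smaller than in that group. The median was lower than in aged dexamethasone mice (difference -0.0152), also with any mouse left out. It was also lower than in young vehicle mice (-0.0124), where the ranges overlapped. The tables were transformed separately and the called genes were not examined apart, so a smaller spread is not excluded against any group. For each mechanical stress gene the SD in the non-stimulated legs was divided by that in the stimulated legs. The median of these ratios was 1.41, 1.27 and 1.13 in young vehicle, young dexamethasone and aged dexamethasone mice. It was 1.19 in aged vehicle mice, so it did not set these apart. The median SDs of the non-stimulated and stimulated legs were 0.51 and 0.4 in young vehicle and 0.5 and 0.35 in young dexamethasone mice. They ran the other way in aged vehicle (0.31 and 0.34) and aged dexamethasone mice (0.33 and 0.44). A difference by age or treatment stays open and was not tested.

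Regrouping the libraries showed which counts chance can give. For dexamethasone in young mice 2 of 100 splits gave as many genes as the real one (191), the other giving 592. In aged mice 1 of 100 did, the real one (827, highest other 5). Shared calls at both ages were 123, also reached by 1 of 100, the real one (highest other 18). Among the 100 splits drawn, random regrouping thus did not reach the aged or the shared count. For the young count a split not made by treatment gave more calls, so this count alone does not exclude chance. In aged mice, which share no library, all 126 higher young calls and 58 of 60 lower ones had the same sign. Both sets passed camera there with an estimated correlation (adjusted p 7.21e-05 and 7.22e-06). These values argue against chance for the young calls as a set, not for each gene. The young split with 592 genes set vehicle mice 5 and 6 and dexamethasone mice 3 to 6 against the rest, which points to a structure of the samples that the labels do not give. It holds 4 of 6 dexamethasone and 2 of 6 vehicle libraries in one group, so it is partly aligned with treatment, and the young calls, and those shared with aged mice, were not adjusted for it. For contraction in aged vehicle mice 1 of 32 splits that part the legs of every mouse gave as many genes as the real one (273, highest other 0). That is 3.1%, the smallest share that 32 splits can give. It was found in 1 of 4 contraction comparisons, with no adjustment for their number. With that limit chance is not excluded. The calls also ended without mouse 2, 3, 5 or 6, which does not itself test chance, since fewer mice were compared. The counts of 0 in young vehicle, young dexamethasone and aged dexamethasone mice are reached by any split, 32 of 32, so these say nothing about chance (highest other 5, 7 and 7). The number of gene lists passing camera at the preset correlation did not exclude chance in any comparison. As many lists passed in 87 and 75 of 100 splits for dexamethasone in young (5; highest other 17) and aged mice (7; 19), and with contraction in 14 of 32 in young vehicle (12; 18), 14 in young dexamethasone (11; 15), 7 in aged vehicle (15; 19) and 17 in aged dexamethasone mice (10; 15).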
